A study of Solanum lycopersicum and Solanum pimpinellifolium with 30 samples.

How the data were processed

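Transcript levels were measured in the pericarp of ripe red tomato fruit on 30 one-colour Affymetrix tomato GeneChips. Per the labels, plants of 10 cultivars were grown in a replicated field trial, the outer skin, locule tissue and seeds were removed from the fruit, total RNA was extracted with Trizol, and biotin-labelled cRNA was hybridised. Each cultivar had 3 biological replicates. The deposited values were log2 signals of 10209 probe sets, normalised by the authors with a method not given in the sources used here. The software, background correction and summarisation are likewise not given. The base of the logarithm is not stated. It was taken as 2, since the spiked bacterial control transcripts step by about the log2 of their standard amounts (median slope 0.958, from 0.51 to 1.19). The deposited values ranged from -0.42 to 12.55. Arrays give no counts, so the number of arrays limits the precision of each value.

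The array medians of the deposited values ran from 1.28 to 1.79, a gap of 0.51. A rule chosen before the data were examined called for quantile normalisation where this gap exceeded 0.5, and all values were therefore quantile normalised between arrays. The 171 control probe sets (108 Affymetrix controls and 63 probe sets for foreign reporter sequences) were left out of the tests, which covered 10038 probe sets. The background of each array was the percentile 95 of its 63 reporter probe sets, and it ran from 0.37 to 2.41. Where arrays of the lower side lay at or below it in most of its arrays or in 2 or more landraces, a fold change is given as a bound, with these arrays raised to that background, and a range of landrace means likewise. For a range the arrays of all landraces were raised, and it is given as a bound only where the highest landrace lay clearly above background.

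The platform annotation of 2007 named 909 of the tested probe sets with 803 gene symbols. The other 9129 probe sets carried no gene name and enter the counts only. Of the named probe sets, 885 matched the reference gene table of the assembly SLM_r2.1 by gene identifier and 24 did not. Genome positions are those of that assembly. The reference gave no gene descriptions, so gene lists were matched on symbols and synonyms, and a symbol that is only a placeholder for a locus counted as undescribed. This left 743 described probe sets for 661 genes. Where a gene had several probe sets, the one with the highest mean over the 30 arrays stood for it in the lists.

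The tests used limma 3.58.1 with statmod 1.5.0 in R 4.3.3, with 1 mean per cultivar, empirical Bayes variances and a Benjamini-Hochberg adjusted p threshold of 0.05, all two-sided. LA1589 was compared with the equally weighted mean of the 9 landraces in a fit of all 30 arrays (20 residual degrees of freedom). Equality of the 9 landrace means was tested with the moderated F test on their 27 arrays (18 residual degrees of freedom). In the same fit each landrace was compared with the mean of the other 8. All 45 pairs of cultivars were also compared. Correlations and permutation tests used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

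The comparisons, their tests, 16 gene lists and the rule for named genes were chosen before the data were examined. The lists were carotenoid, ethylene and ripening regulators, cell wall, sugar and starch, organic acid and GABA, phenylpropanoid and flavonoid, aroma volatiles, ascorbate with tocopherol and antioxidant enzymes, heat shock, defence and wound, photosynthesis, seed tissue, epidermis and cuticle, fruit size and shape, sterol and glycoalkaloid, and cytosolic ribosomal proteins. One match, gad2 in the sterol list, was removed on its name. The 12 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. The ribosomal list had 0 measured genes. Fisher's exact test compared the share of list members past the F test with that of other named genes.

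The named genes were chosen as follows. For LA1589 they were the 10 highest and 10 lowest changes past the threshold in described genes for which all 3 LA1589 arrays lay on the same side of every landrace mean. Among the landraces they were the 12 largest ranges of landrace means past the F test. From each list up to 2 passing members with the largest change or range were added. For each landrace they were the 2 highest and 2 lowest passing changes. Members named as not passing were taken from those with the highest mean level.

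The alternatives tried were the values as deposited, median centring, removal of the dimmest probe sets (2510 of 10038 by mean level), an intensity trend with a robust prior, array weights, removal of probe sets that can cross-hybridise, a replicate block, leaving out each array or landrace in turn, other error terms for LA1589, LA1589 added to the comparison group of each landrace, and the mean of a gene's probe sets in place of 1. Settings added after seeing the data were the mean of the 21 spiked control probe sets as a covariate, removal of landrace 557, a requirement of signal above background in at least 1 cultivar, and leaving out each array in turn for the list calls in single landraces. The fits were tested on simulated data of 10038 probe sets. These were independent of each other, with noise of the size seen within cultivars, and the cultivars differed only where a shift was planted. The shares of false calls therefore do not cover the spread between landraces or the correlation between genes in the real data. For LA1589 against the landraces, 83 of 100 probe sets shifted by 1 on the log2 scale were called, and 16 of 226 calls were false. For the F test, 30 of 100 were called at a shift of 1 and 91 of 100 at a shift of 2, and 5 of 131 calls were false.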

Results

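The data are 30 array profiles of ripe fruit pericarp, 3 biological replicates from each of 10 cultivars. The 9 Andean landraces of Solanum lycopersicum are 3806, 3815, 3836, 3842, 549, 557, 560, 571 and 572. LA1589 is an accession of Solanum pimpinellifolium, a small-fruited wild relative of the cultivated tomato. The share of probe sets above the background of the foreign reporter probe sets, as a cultivar mean, ran from 48.5% in 557 to 72.0% in 3806. The correlation of an array with the other arrays of its cultivar, after removal of control probe sets, ran from 0.917 to 0.990, and 26 of the 30 arrays were nearest to an array of their own cultivar. The mean of the spiked bacterial controls ran from 7.24 ± 0.25 in 571 to 9.82 ± 0.32 in 557 (log2, SD, n = 3 arrays each). It was 9.70 ± 0.27 in 572 and 8.94 ± 0.48 in LA1589. Whether the amount of cRNA, the amount of the controls and the day of hybridisation were the same for all arrays is not given, so this mean can follow any of these. Values of the tested probe sets are log2 signals after quantile normalisation, unless another scaling is named. Those of the spiked controls and of single control probe sets are as deposited.

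The first comparison asks how the ripe fruit of the wild accession differs from that of the landraces. Defence genes were among those with the highest changes in LA1589. The chitinase gene CHI14 was higher by 3.87 ± 0.33 (log2 difference, SE, 3 against 27 arrays; adjusted p = 6.7e-09), with 4.79 ± 1.21 (SD) in LA1589 against a landrace mean of 0.92, and with 2 landraces at background it was at least 13.0-fold higher. Without replicate 2 of LA1589 the difference was 4.57. NP24-I, an osmotin-like pathogenesis-related protein, was higher by 3.71 ± 0.52 (adjusted p = 1.59e-05) and reached 10.51 ± 0.33. Its landrace means ran from 4.22 in 549 to 9.38 in 571. In limma with 1 mean per cultivar its adjusted p was 0.401. The alpha-galactosidase gene AGAL was higher by 4.54 ± 0.19 (adjusted p = 1.6e-14), with 4.89 ± 0.54 against 0.35. As 6 of the 9 landraces lay at background for AGAL, it was at least 17.2-fold higher. PME2.1 and PE1, pectin methylesterase genes of the cell wall list, were lower. PME2.1 fell by 5.08 ± 0.37 (adjusted p = 6.56e-10) to 0.45 ± 0.16, which is at background, so that it was at least 23.9-fold lower. PE1 fell by 3.27 ± 0.27 (adjusted p = 3.5e-09), from 8.09 to 4.82 ± 0.62. PME2.1 and PE1 each had 1 probe set, so no other probe set could check for mismatches with the LA1589 sequence. PMEU1, a further pectin methylesterase gene that was picked after its values were seen, did not pass (1.12, adjusted p = 0.0884).

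The other genes higher in LA1589 were CHI9, a further chitinase gene (3.33), PCNA, the sliding clamp of DNA replication (2.26), RDRP, an RNA-dependent RNA polymerase (1.86), EIN2 of ethylene signalling (1.85), the catalase gene CAT2 (1.77), STC (1.72) and FPPS1, a farnesyl diphosphate synthase (1.62). Their adjusted p ran from 5.76e-06 for PCNA to 0.00872 for CHI9. The other lower genes were E8, a gene induced in ripening (-2.53), the malate dehydrogenase gene mdh (-2.25), NCED1 of abscisic acid synthesis (-2.05), the remorin gene rem-1 (3.96 against 5.96), WRKYIId-1 (-1.89), the catalase gene cat1 (-1.82) and THOX2 (-1.72). Their adjusted p ran from 3.41e-07 for rem-1 to 0.0049 for mdh. Each of these lower genes was also read on 1 probe set only. NCED1 was at background in LA1589 and at least 3.20-fold lower. The metallothionein gene MT4 had the largest fall of the genes named by the rule, 7.10 ± 0.24 (adjusted p = 1.72e-16) on 1 of its 4 probe sets. The other 3 MT4 probe sets differed by -0.60, -0.39 and -0.32 and did not pass (adjusted p = 0.213, 0.347 and 0.396).

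The AGAL gene lies on chromosome 3 from 58140026 to 58145870, CHI14 on chromosome 2 from 49437787 to 49439565, and NP24-I on chromosome 8 from 66041684 to 66042671. PE1 and PME2.1 lie on chromosome 7, from 68876047 to 68878306 and from 68885752 to 68888084. In the cultivated tomato assembly, E8 lies on chromosome 3 from 54382264 to 54383995 and MT4 on chromosome 6 from 49782881 to 49783905.

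**Figure D1:**
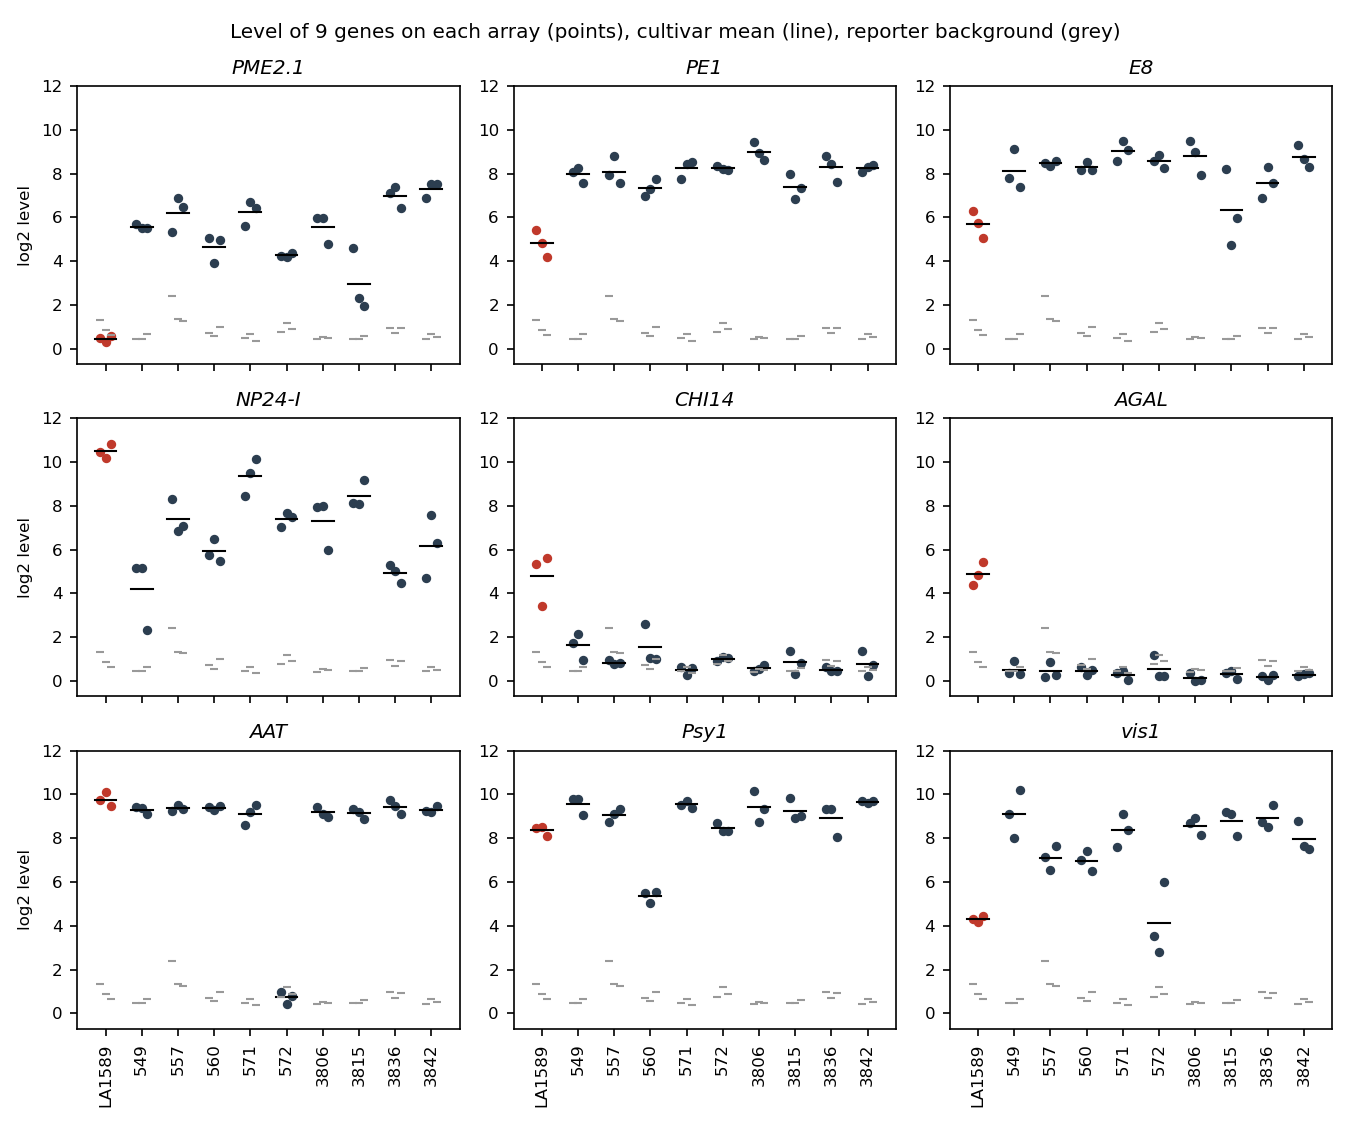
Log2 signal of 9 named genes on each array by cultivar, with LA1589 in red, lines at the cultivar means and the reporter background in grey. AAT was at 0.74 in landrace 572 against 9.09 to 9.44 in the other landraces, and PME2.1 was at 0.45 in LA1589.

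Among 37 ethylene and ripening regulators 10 were higher in LA1589, 3 were lower and 24 did not pass. Adjusted over the list alone, 10 were higher and 4 lower. ACS2, which makes the ethylene precursor, rose by 2.53 ± 0.62 (adjusted p = 0.00659; 3.11 without replicate 2 of LA1589) and E8 fell. The ACS2 level in LA1589, 7.45 ± 1.01, lay within the landrace means, which ran from 2.70 in 3806 to 7.60 in 557. The ethylene receptor gene ETR3 did not pass (0.03, adjusted p = 0.95). Among 39 cell wall genes 4 were higher, 4 lower and 31 did not pass, and adjusted over the list alone 5 were higher and 5 lower. PME2.1 and PE1 were the members with the largest falls, and the polygalacturonase gene PG2 did not pass (-0.65, adjusted p = 0.408). Of 17 carotenoid genes 1 was higher, 3 were lower and 13 did not pass, with the same counts adjusted over the list alone. NCED1 and DXS, the entry enzyme of plastid isoprenoid synthesis (-1.53, adjusted p = 0.0132), were lower, while phytoene synthase Psy1 did not pass (-0.44, adjusted p = 0.265). Of 17 defence and wound genes 5 were higher, 0 were lower and 12 did not pass. Adjusted over the list alone 6 were higher. LAPA2 did not pass (0.41, adjusted p = 0.105).

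Of 22 sugar and starch genes 2 were higher, 2 lower and 18 did not pass, and the counts adjusted over the list alone were 2 and 2. The acid invertase gene AI was higher by 1.36 ± 0.44 (adjusted p = 0.0371). The sucrose transporter gene SUT4 was at least 1.95-fold higher (adjusted p = 2.54e-05), with 3 of the 9 landraces at background, and its other probe set was too dim to compare (0.40 against 0.55). Of 11 ascorbate, tocopherol and antioxidant genes 3 were higher, 1 lower and 7 did not pass, and adjusted over the list alone 3 were higher and 3 lower. The catalase genes CAT2 and cat1 moved in opposite directions, and the superoxide dismutase gene SODCC.1 did not pass (0.14, adjusted p = 0.558). Of 10 aroma volatile genes 2 were higher, 0 lower and 8 did not pass, with the same counts adjusted over the list alone. The lipoxygenase gene TomloxE was higher by 1.36 ± 0.40 (adjusted p = 0.0212). The alcohol acyltransferase gene AAT, which makes aroma esters, was higher by 1.44 ± 0.16 (adjusted p = 7.64e-07). Its level in LA1589 was 9.77 ± 0.32 against 9.09 to 9.44 in 8 landraces and 0.74 in 572, which lowers the landrace mean.

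Of 6 heat shock genes 0 were higher and 1 was lower, vis1, a small heat shock protein gene (-3.46 ± 0.45, adjusted p = 5.93e-06), with 4.31 ± 0.15 in LA1589. This lay within the landrace means of vis1, which ran from 4.11 in 572 to 9.10 in 549. Of 9 photosynthesis genes 0 passed in either direction, over all probe sets or adjusted over the list alone, and PSBR differed by -0.03 (adjusted p = 0.959). Of 6 phenylpropanoid genes 1 was higher and 5 did not pass. It was hqt of chlorogenic acid synthesis (1.61 ± 0.32, adjusted p = 0.0011). Of 9 organic acid and GABA genes mdh alone was lower and 8 did not pass, among them the malic enzyme gene ME1 (-0.43, adjusted p = 0.257). Of 12 fruit size genes 2 passed and 10 did not. krp2 was at least 1.75-fold higher, with 2 landraces at background (adjusted p = 0.00197). CycA1 passed (0.69 against 0.31, adjusted p = 0.0123), but all 9 landraces and 2 of the 3 LA1589 arrays lay at background, so that it is not given as higher. Of 4 sterol genes FPPS1 was higher and SlSSR1 lower (-1.10, adjusted p = 0.000222). For these last 5 lists and the sterol list the counts adjusted over the list alone were the same. The seed gene TAS14 (-0.25, adjusted p = 0.459) and the epidermis genes LE16 (0.35, adjusted p = 0.621) and TSW12 (0.08, adjusted p = 0.817) did not pass, and adjusted over their lists alone 0 passed.

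Of the 12 tested lists 0 passed the camera test, with 2 at an unadjusted p under 0.05, defence and wound (adjusted p = 0.147) and heat shock (adjusted p = 0.171). With an estimated correlation 0 passed, with the lowest adjusted p = 0.614. The fry test, which asks whether the members move on balance in 1 direction and does not compare them with other genes, passed 5 lists. These were defence and wound (adjusted p = 0.000294), ascorbate (0.00592), sugar and starch (0.0322) and aroma (0.0386) upward, and heat shock (0.0368) downward. Median and mean change differed in sign for ethylene and ripening regulators (-0.01 and 0.04), cell wall (0.00 and -0.18), phenylpropanoid (-0.02 and 0.16), fruit size (-0.03 and 0.11), sterol (-0.15 and 0.05) and organic acid genes (0.00 and -0.18). Camera followed the mean in all of these that were tested.

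In limma 1560 of 10038 probe sets (15.5%) passed, 861 higher and 699 lower in LA1589. By 2-fold or more, 639 passed, 317 higher and 322 lower. Of the 803 named genes 160 passed, 99 higher and 61 lower. With median centring 1720 passed, 1135 higher and 585 lower, and by 2-fold or more 358 higher and 298 lower. A single wild accession was measured. With 1 mean per cultivar, so that the spread between landraces is the error, 111 probe sets passed and 87 of them by 2-fold, and with cultivar as a random effect 228 and 202. Without replicate 1 of LA1589 888 passed. Of the 31 genes named by the rule 26 lost the threshold with 1 mean per cultivar, and 19 lost it with the random effect. The exceptions with 1 mean per cultivar were AGAL, CHI14, PE1, SUT4 and MT4, the last on 1 of its 4 probe sets. Without replicate 1 of LA1589 the adjusted p was 0.0784 for CHI9, 0.0553 for DXS, 0.0730 for ACS2, 0.0565 for AI and 0.274 for TomloxE. Without replicate 2 it was 0.0634 for mdh, 0.333 for AI and 0.0693 for CycA1. Without replicate 3 it was 0.137 for DXS, 0.0573 for ACS2, 0.0906 for TomloxE and 0.0755 for CycA1. With the values as deposited it was 0.0656 for AI, and with array weights 0.174 for AI and 0.119 for TomloxE. With the spiked controls as a covariate it was 0.0940 for CHI9 (log2 difference then 2.27), 0.0580 for mdh (-1.61), 0.141 for DXS (-0.95), 0.0915 for TomloxE (1.22) and 0.0550 for CycA1.

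The second comparison asks which transcripts differ among the landraces. AAT had the largest range of landrace means, from 0.74 ± 0.27 in 572 to 9.44 ± 0.31 in 3836 (SD, n = 3 arrays each; limma F test adjusted p = 2.38e-17), and as 2 arrays of 572 were at background this is at least 342-fold. Man4, an endo-beta-mannanase of the cell wall, ran from 0.53 ± 0.84 in 3815 to 6.53 ± 0.76 in 560 (adjusted p = 0.000692), at least 51.4-fold with 2 arrays of 3815 at background. The plastocyanin gene PETE ran from 2.82 ± 2.47 in 3815 to 8.33 ± 0.14 in 560 (adjusted p = 0.000337). Its range of 5.51 was 6.30 without replicate 1 of 3806 and 6.91 without replicate 1 of 3815. NP24-I ran from 4.22 ± 1.64 in 549 to 9.38 ± 0.86 in 571 (adjusted p = 0.000154), and its range of 5.16 was 4.44 without replicate 3 of 549. Psy1, which commits carbon to carotenoids, ran from 5.36 ± 0.28 in 560 to 9.66 ± 0.04 in 3842 (adjusted p = 1.92e-07).

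Other genes with large ranges were ACO5 and ACS2 of ethylene synthesis (at least 31.5-fold for ACO5, with all 3 arrays of 560 at background, and 4.91 for ACS2), the xyloglucan endotransglycosylase genes tXET-B2 (at least 35.7-fold, with 2 arrays of 557 at background) and XTH3 (4.88), the small heat shock protein genes vis1 (from 4.11 to 9.10) and MTSHP (range 4.76), TFHS1 (4.65) and DDTFR8 (4.63). ACO5 and ACS2 were highest in 572 and 557, tXET-B2 and XTH3 in 3806, vis1 in 549, MTSHP in 3815, TFHS1 in 572 and DDTFR8 in 549. Their adjusted p ran from 3.17e-05 for DDTFR8 to 0.00293 for tXET-B2. Single arrays moved these ranges, while each gene passed. Not raised to background, the range of ACO5 was 5.32, 4.34 without replicate 1 of 572 and, as a fold, 1.84 times wider without its replicate 2, and that of tXET-B2 was 5.31, and 5.99 without replicate 2 of 572. The range of vis1 was 4.35 without replicate 2 and 5.93 without replicate 3 of 572, and that of XTH3 was 5.72 without replicate 2 of 572. Without replicate 1 of 3806 it was 4.21 for ACS2 and, as a fold, 1.56 times wider for MTSHP, and without replicate 3 of 557 it was 5.34 for DDTFR8.

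By list, 8 of 10 aroma genes passed the F test, among them AAT and LOX1.1 (range at least 11.2-fold, with all 3 arrays of 572 at background, adjusted p = 0.00946). Of 6 heat shock genes 5 passed, among them HSP17.4, from 4.74 ± 0.81 in 557 to 8.74 ± 0.63 in 3815 (adjusted p = 0.000242). Of 9 photosynthesis genes 6 passed, and 7 adjusted over the list alone, with PSBO from 3.62 ± 2.02 in 3815 to 7.33 ± 0.53 in 549 (adjusted p = 0.00567). Of 11 ascorbate genes 7 passed, with CAT2 (range 2.95) and DHAR1 (1.96) first. Of 37 ethylene and ripening regulators 21 passed (24 adjusted over the list alone), of 17 carotenoid genes 9, with Psy1 and CrtR-b1 (2.56) first, and of 39 cell wall genes 16 (18 adjusted over the list alone). Of 22 sugar and starch genes 6 passed, with AI (3.09) and sus3 (2.18) first, and of 9 organic acid genes 3, with mdh (2.99) and GABA-TP3 (2.98) first. Of 17 defence genes 4 passed (3 adjusted over the list alone), with NP24-I and CHI17 (4.35) first. With 1 array left out the range was 4.81 for HSP17.4 (replicate 1 of 3806), 4.88 and 3.07 for PSBO (replicates 1 and 2 of 3815), 3.59 for CAT2 (replicate 2 of 549), 3.93 for mdh (replicate 1 of 3815), 4.44 for NP24-I (replicate 3 of 549), and 3.26 and 5.04 for CHI17 (replicates 1 and 3 of 3815). All of these passed.

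Of 6 phenylpropanoid genes hqt alone passed (3.33, and 4.03 without replicate 2 of 549), and of 4 sterol genes 2 passed, FPPS1 (2.31) and SlSSR1 (1.56). Of 12 fruit size genes 2 passed, and 1 adjusted over the list alone. They were CycA3 (1.19, adjusted p = 0.0342) and krp2 (1.11, adjusted p = 0.00828). For krp2, landraces 557 and 3836 lay at background, so its range is uncertain and is not given as a bound. CycA3 lost the threshold when 1 array was left out, for replicate 1 or 3 of 557 (adjusted p = 0.0712 and 0.0689), replicate 2 of 572 (0.0745), replicate 1 of 560 (0.0507), replicate 3 of 3806 (0.0503) and replicate 2 of 3815 (0.0521). Without replicate 2 of 557 its range was 1.90. With the spiked controls as a covariate its adjusted p was 0.435. The seed gene and the epidermis genes did not pass. For the lists given without a count adjusted over the list alone, that count was the same. Fisher's exact test passed 0 of 12 lists after adjustment, with 1 at an unadjusted p under 0.05, the aroma list with 80% of its genes against 43.5% of other named genes (p = 0.0257, adjusted p = 0.272).

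The F test called 3921 of 10038 probe sets (39.1%), 3266 of them with a range of at least 1, and 353 of the 803 named genes. With median centring 6252 passed.

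The third comparison asks which landraces stand apart. In 572 AAT fell by 8.53 ± 0.16 against the mean of the other 8 (log2, SE, 3 against 24 arrays; adjusted p = 1.18e-20), and as 2 of its 3 arrays were at background it was at least 304-fold lower. AAT had 1 probe set, so no other probe set could check this fall. The AAT gene lies on chromosome 8 from 1383748 to 1386747. In 572 vis1 fell by 4.12 ± 0.47 (adjusted p = 5.29e-06) to 4.11, against 6.97 to 9.10 in the other landraces, while ACO5 (3.91, adjusted p = 0.000817) and TFHS1 (3.03, adjusted p = 7.45e-05) rose. The difference of vis1 was -3.47 without replicate 2 and -5.05 without replicate 3 of 572, and that of ACO5 was 2.94 without replicate 1 and 4.79 without replicate 2, all passing. In 560 Psy1 fell by 3.87 ± 0.26 (adjusted p = 1.24e-09) to 5.36, 14.6-fold lower, against 8.46 to 9.66 in the other landraces and 8.36 in LA1589. A second Psy1 probe set fell by 1.90 in 560 (adjusted p = 1.34e-06), and another, dim one differed by -0.05 (adjusted p = 0.843). Psy1 lies on chromosome 3 from 5586036 to 5591181. Also in 560, MTSHP fell by 3.43 (adjusted p = 0.000137), and PETE (3.12, adjusted p = 0.00192) and Man4 (3.02, adjusted p = 0.00461) rose. With the spiked controls as a covariate PETE (1.90) and Man4 (2.14) passed with smaller differences.

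In 557 ACS2 rose by 3.01 (adjusted p = 0.00204) to 7.60 ± 0.43, TSI-1 rose at least 4.19-fold, since 7 of the other 8 landraces lay at background, to 2.72 with an SD of 3.06 between its arrays (adjusted p = 0.00601), and DDTFR8 (-3.45, adjusted p = 1.52e-05) and HSP17.4 (-3.09, adjusted p = 0.00032) fell. The rise of TSI-1 rests on replicate 1 (6.19), since replicate 2 (0.43) lay at background and replicate 3 was at 1.53. Its difference was 2.36 with all arrays, 0.63 without replicate 1, 3.51 without replicate 2 and 2.95 without replicate 3. That of DDTFR8 was -4.16 without replicate 3. With array weights ACS2 and TSI-1 lost the threshold (adjusted p = 0.0747 and 0.0892, with differences of 3.04 and 1.41). With the spiked controls as a covariate the adjusted p in 557 was 0.120 for ACS2, 0.493 for TSI-1 and 0.0701 for DDTFR8, while the log2 differences were 3.48, 1.51 and -2.66. HSP17.4 passed with -3.77. In 572 it was 0.252 for ACO5 and 0.363 for TFHS1, with differences of 2.97 and 1.24. In 549 the fatty acid desaturase gene Fad7 (2.38, adjusted p = 0.000958) and CAB4, a chlorophyll a/b binding protein gene (1.89, adjusted p = 0.00215), rose, and SIP (-2.25, adjusted p = 0.000984) and NP24-I (-2.91, adjusted p = 0.00658) fell. Without replicate 3 of 549 NP24-I lost the threshold (-1.96, adjusted p = 0.132), and with array weights it passed with -2.31.

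In 3806 tXET-B2 rose by 3.81 (adjusted p = 0.00364) and RSI-1 fell by 3.17 (adjusted p = 0.00164), with differences of -4.08 without replicate 2 of 3806 and -3.99 with array weights. XTH3 (2.82, adjusted p = 0.0149) lost the threshold without replicate 1 (0.0738) or 3 (0.0832) of 3806, and PETE (-2.78, adjusted p = 0.0202) without replicate 2 (-1.59, 0.371) or 3 (-2.90, 0.0872). The difference of PETE was -3.84 without replicate 1 and -4.53 with the spike covariate, both passing. In 3815 h52 rose at least 5.71-fold, with 4 of the other 8 landraces at background (adjusted p = 8.5e-05). Not raised to background, its difference was 2.84, and 3.43 without replicate 1 of 3815. The chitinase gene CHI17 (3.01, adjusted p = 0.0161) lost the threshold without replicate 1 (1.91, 0.164) or 2 (3.42, 0.0550) of 3815, Man4 (at least 10.7-fold lower, with 2 of 3 arrays at background, adjusted p = 0.0034) without replicate 2 (0.0524), and PETE (-3.08, adjusted p = 0.00707) without replicate 2 (-2.65, 0.106) or 3 (-2.12, 0.176). CHI17 passed with 3.69 without replicate 3, and PETE with -4.48 without replicate 1 and -3.81 with array weights.

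In 571 ER1 (3.20, adjusted p = 0.0227) and NP24-I (2.90, adjusted p = 0.0118) were higher, and CAT2 (-1.62, adjusted p = 0.0152) and GAI (-1.53, adjusted p = 0.0358) lower. Each lost the threshold without replicate 2 of 571 (adjusted p = 0.116, 0.0901, 0.163 and 0.222) and without replicate 3 (0.179, 0.112, 0.0796 and 0.107). ER1 (0.0582) and GAI (0.213) also lost it without replicate 1, and GAI without replicate 2 or 3 of 3842 (0.0503 and 0.0520). In 3836 ERF2 (1.88, adjusted p = 0.017), an ethylene response factor gene, and PME2.1 (1.62, adjusted p = 0.0255) were higher, and Man4 (-2.85, adjusted p = 0.0376) and the ethylene synthesis gene ACS4 (-2.49, adjusted p = 0.0262) lower. Without replicate 1 of 3836 their adjusted p was 0.0629, 0.117, 0.109 and 0.0740. Without replicate 2 it was 0.0870 for ERF2, 0.173 for PME2.1 and 0.152 for Man4, and without replicate 3 it was 0.0701 for ERF2, 0.141 for Man4 and 0.229 for ACS4. The difference of ACS4 was -3.11 without replicate 2, where it passed, and -1.62 without replicate 3. With the spiked controls as a covariate the 4 genes of 571 (adjusted p from 0.172 to 0.817) and the 4 of 3836 (from 0.0593 to 0.396) lost the threshold. The log2 differences were then 4.29 for ER1, 3.44 for NP24-I, -1.22 for CAT2 and -0.78 for GAI in 571, and 1.69 for ERF2, 1.98 for PME2.1, -1.67 for Man4 and -1.52 for ACS4 in 3836.

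In 3842 PME2.1 was higher, with 7.30 ± 0.38 against a mean of 5.31 (adjusted p = 0.0324), and no lower gene was named by the rule. PME2.1 lost the threshold without replicate 1 (0.116), 2 (0.496) or 3 (0.295) of 3842, without replicate 3 of 549 (0.0511), with median centring (0.0571), with a replicate block (0.0504) and with the spiked controls as a covariate (0.999, with a difference of 1.49). AAT passed in 3842 (1.10, adjusted p = 0.00635), but its level of 9.30 lies within the range of the landraces other than 572. It lost the threshold without replicate 1 (0.0684) or 3 (0.0859) of 3842 and with the spike covariate (0.227, with a difference of 0.98).

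Of 108 camera tests of a list in a landrace 10 passed at the preset correlation, 5 of them for photosynthesis and 4 for heat shock genes. With an estimated correlation 0 held (adjusted p from 0.704 to 0.752), and 5 of the 108 tests had an unadjusted p under 0.05, among them photosynthesis in 549 and 3815. At the preset correlation photosynthesis genes were higher as a list in 549 (camera adjusted p = 1.08e-06, 2 of 9 members higher and 0 lower) and in 560 (0.0443, 4 higher and 0 lower). With an estimated correlation the adjusted p was 0.704 in 549 and 0.752 in 560. They were lower in 3815 (3.5e-05, 5 lower), 3806 (0.0227, 1 lower) and 3836 (0.0311, with 0 members passing singly). With an estimated correlation the adjusted p was 0.704 in 3815 and 0.713 in 3806 and 3836. Heat shock genes were lower in 557 (0.0355, 3 of 6 lower) and 560 (0.0311, 3 lower), and higher in 3815 (0.0311, 1 higher) and 3836 (0.0227, with 0 passing singly). In all 4 the adjusted p was 0.704 with an estimated correlation. Carotenoid genes were higher in 549 (0.00381, 1 of 17 higher; adjusted p = 0.704 with an estimated correlation). The replicates of 3815 differed, with photosynthesis means of -0.23, -1.63 and -1.94 relative to the landraces, and those of 3806 with -0.06, -1.43 and -0.74. When 1 array at a time was left out, a check added after seeing the data, photosynthesis in 549 and 3815 and carotenoid genes in 549 passed each time. Photosynthesis in 3806 lost the threshold without its replicate 2 (adjusted p = 0.168), and in 3836 without its replicate 1 (0.0607) or 3 (0.203). In 560 it lost it without replicate 1 or 2 of 549, 557 or 560, replicate 1 of 571 or 572, replicate 2 of 3806, replicate 3 of 3815, or replicate 1 or 3 of 3836 (adjusted p from 0.0507 to 0.142). Heat shock genes lost it in 3815 without its replicate 2 (0.202) and in 3836 without its replicate 3 (0.0763). In 557 they lost it without its replicate 1 (0.0638) or 2 (0.0929), replicate 2 of 3806 (0.0517) or replicate 3 of 3836 (0.0599), and in 560 without its replicate 3 (0.0560) or replicate 3 of 3836 (0.0547). Over the 27 landrace arrays, within landraces, the photosynthesis mean correlated with the spiked controls with r = -0.612 (permutation p = 0.0169, adjusted p = 0.0506).

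**Figure D2:**
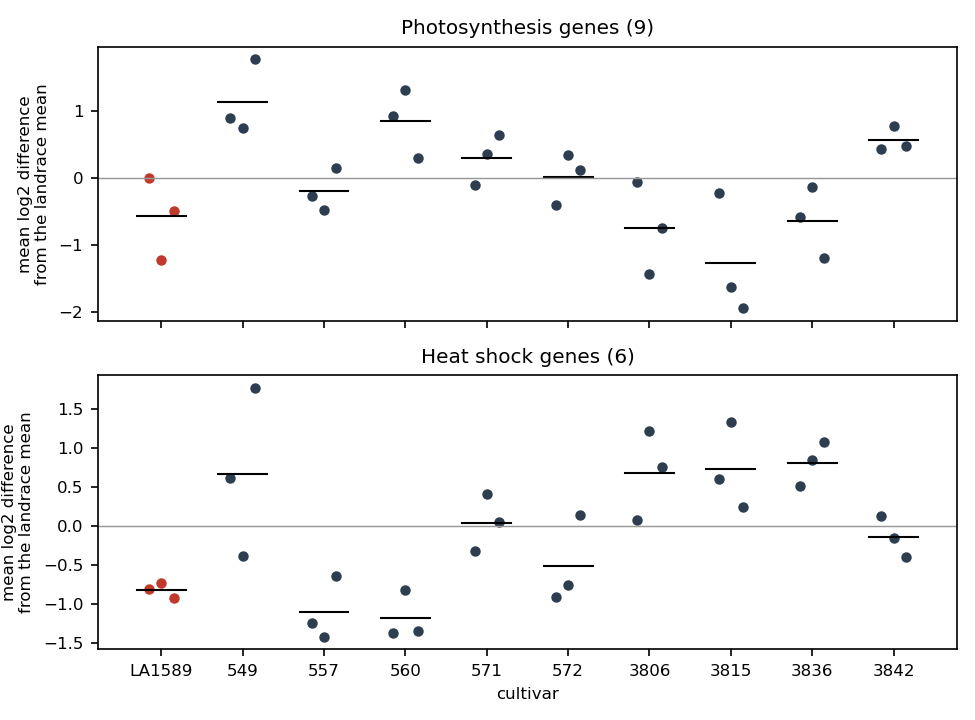
Mean log2 level of 9 photosynthesis and 6 heat shock genes on each array, relative to the mean of the landraces. The photosynthesis mean was 1.13 in 549 and -1.27 in 3815.

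The number of probe sets past the threshold against the other 8 was 2347 for 557 (1230 higher, 1117 lower), 2270 for 560 (1184 and 1086), 1402 for 572 (737 and 665), 833 for 3815 (460 and 373), 578 for 3806 (312 and 266), 381 for 3836 (206 and 175), 151 for 549 (84 and 67), 75 for 571 (41 and 34) and 16 for 3842 (8 and 8). The division by direction moved with the scaling and other settings. With the values as deposited it was 1415 higher and 1812 lower for 557, 129 and 27 for 571, 676 and 933 for 572, 454 and 222 for 3806, 179 and 206 for 3836, and 9 and 5 for 3842. With median centring it was 2556 and 1302 for 557, 32 and 66 for 571, 2152 and 562 for 572, 253 and 569 for 3806, and 377 and 112 for 3836. Without the dimmest probe sets it was 892 and 1094 for 557. With array weights it was 1552 and 1607 for 560 and 1605 and 1650 for 3806.

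With the spiked controls as a covariate the counts were 286 for 557, 339 for 572, 76 for 549, 5 for 571, 880 for 3806, 21 for 3836 and 1 for 3842. With array weights they were 295 for 557, 771 for 549, 694 for 571, 3255 for 3806, 1782 for 3815, 728 for 3836 and 1029 for 3842. Some counts rested on single arrays. They were 1292 without replicate 1 of 557, 1441 without replicate 1 of 560 and 847 without replicate 1 of 572. For 549 the count was 38 without its replicate 1, 53 without its replicate 3 and 237 without replicate 1 of 3815. For 3806 it was 115 and 140 without its replicates 2 and 3, and for 3815 it was 211 and 186. For 3836 it was 64, 56 and 177 without its replicates 1, 2 and 3, and 574 without replicate 3 of 549. For 571 it was 19, 21 and 30 without its own replicates, 113 and 114 without replicates 1 and 2 of 557, 115 without replicate 1 of 3815, and 44 without replicate 2 or 3 of 3842. For 3842 it was 0, 2 and 0 without its own replicates and 61 without replicate 1 of 3815.

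**Figure D3:**
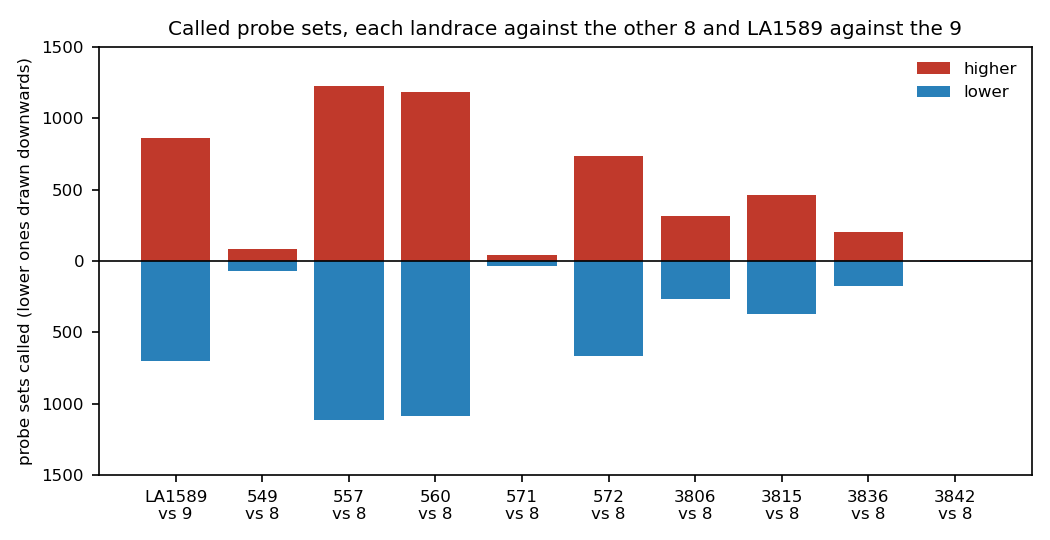
Probe sets past the threshold that were higher (upward bars) or lower (downward bars) in LA1589 against the 9 landraces and in each landrace against the other 8. The counts ran from 16 for 3842 to 2347 for 557.

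The distance between cultivars was described by the number of probe sets past the threshold in each pair. The 36 pairs of landraces ran from 3 to 2204, with a median of 698.5, and the 9 pairs with LA1589 ran from 990 to 1738, with a median of 1204. The closest pairs were 549 with 3842 (3), 571 with 3842 (9) and 549 with 571 (25), and the farthest were 560 with 3806 (2204), with 3815 (2186) and with 557 (2168). By this count 3815 was the landrace closest to LA1589 (990) and 560 the farthest (1738). By the median absolute difference of cultivar means, 3815 was again the closest to LA1589 (0.27) but 557 the farthest (0.34, against 0.31 for 560). That measure ran from 0.14 to 0.37 between landraces, with the highest value for 557 with 560. Each cultivar compared with the mean of the other 9 gave 2188 probe sets for 557, 2147 for 560 and 1560 for LA1589. The order of 557 and LA1589 depended on the setting. Against the other 8 landraces 557 had 295 probe sets with array weights and 286 with the spike covariate, while LA1589 had 1198 and 1135 against the 9 landraces.

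**Figure D4:**
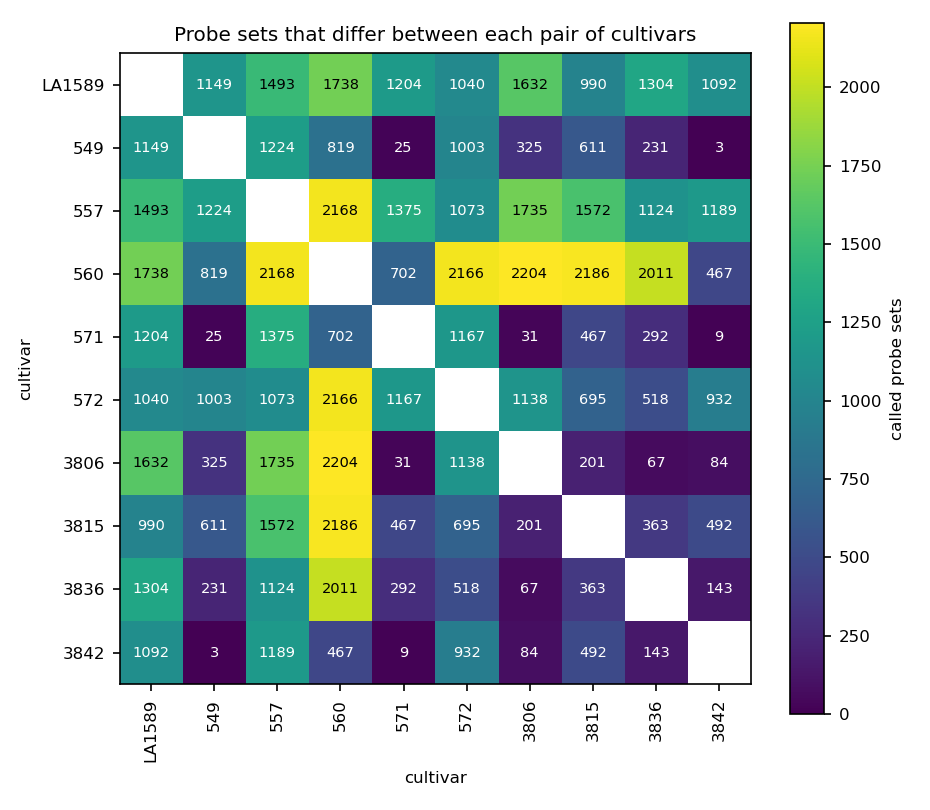
Number of probe sets past the threshold for each of the 45 pairs of cultivars. Pairs of LA1589 with a landrace lie between 990 and 1738, and pairs of landraces between 3 and 2204.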

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

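The test of heat shock against photosynthesis genes was written after its result was seen. The other tests in this part were written before their results.

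Signals outside the tested probe sets, taken as deposited, differed between cultivars. The mean of the spiked bacterial controls differed by 2.58 (log2) between the highest cultivar, 557, and the lowest, 571. A 25S ribosomal RNA probe set differed by 3.03 between its highest and lowest cultivar means, with 5.85 ± 0.19 in 3815 and 6.40 ± 0.49 in LA1589 against 7.87 to 8.88 in the other cultivars (SD, n = 3 each). A probe set for a foreign reporter sequence was 1.98 higher in 557 than the median of the other cultivars, with 3.98 ± 0.73 in 557 and 3.73 ± 0.73 in 572. A second one was 1.87 higher in 557, with 2.52 ± 1.17 against 1.67 ± 0.33 in 572.

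The fall of probe sets in LA1589 may in part come from mismatches between the probes, designed on cultivated tomato, and the LA1589 sequence. If so, other probe sets of the same gene should not share the fall. The median ratio of their change to that of the called probe set was 0.0848, but over 2 genes, MT4 and CYP85A1, with a 95% interval of 0.0695 to 1.35. For probe sets higher in LA1589 the ratio was 0.614 over 8 genes, and for probe sets lower in 1 landrace it was 0.630 over 16 genes. The ratio was under 0.25 for 1 of 9 other probe sets in the former and for 8 of 30 in the latter. For MT4, 2 bright other probe sets stood at 7.98 and 7.06 in LA1589, against landrace means of 8.58 and 7.45. The fall of 7.10 is therefore that of 1 probe set and was not shown for the MT4 transcript as a whole. For the lower probe sets as a set, mismatches cannot be told apart from lower transcript levels here, since 2 genes are too few. A true difference of the wild accession stays open for them as well.

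For landrace 557, which had the highest spiked controls, less labelled target on its arrays could account for part of the called probe sets, if the controls were added in equal amounts, which the sources used here do not state. The dependence on the spiked controls within the other cultivars predicted the differences of the called probe sets with r = 0.226 across probe sets, which are not independent. This lies between the values set as deciding for and against, and the 2 explanations, target amount and landrace, cannot be told apart because all 3 arrays of 557 have high spiked controls. A single array was argued against as the whole source, since 1292 of 2347 probe sets passed without replicate 1, although the count moved by more than 1.5 times. With array weights, which keep all arrays but weight them unequally, 295 passed, so the size of the count depends on the weighting. A difference of the landrace itself was not tested.

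Photosynthesis genes ranged from 1.13 in 549 to -1.27 in 3815, and a possible explanation is fruit picked at different ripeness. The mean of the ripening genes E8, PG2, EXP1, TBG4 and loxC would then run against the photosynthesis mean over the 9 landraces, but r was 0.661 (exact permutation p = 0.0524, adjusted over 3 relations 0.157; rho = 0.650, p = 0.0666), 0.466 without 3815 and 3842, and 0.526 within landraces (permutation p = 0.109, adjusted 0.163; 0.301 without the 2 arrays farthest out). The positive r over the landraces is the opposite of this prediction. The prediction takes these genes to rise steadily with ripeness, which was not measured, so a difference in ripeness stays open. For heat shock genes r was -0.410 (exact permutation p = 0.267, adjusted 0.400; rho = -0.550, p = 0.133; -0.404 without 560 and 557) over landraces and 0.183 within them (permutation p = 0.497), so an opposite movement was not shown. For the spiked controls r was -0.308 (exact permutation p = 0.414, adjusted 0.414; rho = -0.317, p = 0.410; -0.473 without 557 and 572) over landraces and -0.612 within them (permutation p = 0.0169, adjusted 0.0506; rho = -0.583, p = 0.0153, adjusted 0.0459; -0.457 without the 2 arrays farthest out), so target amount stays open. Genetic differences between landraces were not tested against these.

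Random splits of the arrays into groups of the same sizes, 100 with the real one, asked whether chance alone groups arrays as strongly. They mix arrays of different cultivars, so a low share shows that the 3 arrays of a cultivar are alike and differ from the others. For LA1589 1 split, the real one, gave as many probe sets (1560, highest other 107), and 1 by 2-fold (639, highest other 64). This does not set the wild accession apart from a landrace, since each cultivar against the other 9 gave 2188 for 557 and 2147 for 560, with LA1589 after them at 1560. Among the landraces 1 gave as many (3921, highest other 8). Against the other 8 landraces, 1 split gave as many for 557 (2347, highest other 153), 560 (2270, 68), 572 (1402, 271), 3806 (578, 246), 3815 (833, 224) and 3836 (381, 160). There were 2 for 549 (151, highest other 210) and 3 for 571 (75, 159). Each of these shares is under 0.05, without adjustment over the 9 landraces, which excludes a random grouping of arrays and no more. For 549 and 571 other splits nevertheless called more than the real one, so it is excluded less firmly there. For 3842 6 splits gave as many (16, highest other 780), so chance was not excluded. A split can place arrays of another cultivar together, and their real differences are then called. High counts in other splits therefore cannot show whether the samples hold a structure beyond the cultivars.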

How the results depend on the processing

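Settings added after seeing the data were the spike covariate, removal of landrace 557, the requirement of signal above background, and leaving out single arrays for the list calls. The counts for LA1589 by 2-fold or more and for the F test stayed within 1.5 times when any single array was left out. Of 1560 probe sets for LA1589, 1421 were also called with the values as deposited, 1419 with median centring, 1484 without the dimmest probe sets (7528 left), 1120 with array weights and 1008 with the spike covariate. None of the named changes in LA1589 or in a single landrace reversed direction under the settings in which named genes were checked. Ranges among the landraces cannot change sign. Named genes were not checked without a whole landrace or without probe sets that can cross-hybridise. Nor were they checked with signal required above background or with LA1589 in the comparison group. With median centring the median difference of all probe sets was 0.11 for LA1589, 0.13 for 557, -0.16 for 571, 0.21 for 572, -0.18 for 3806 and 0.12 for 3836, against -0.04 to 0.01 with quantile normalisation over all comparisons, and the directions given are relative to these. The share of probe sets above background, 48.5% in 557, limits which falls can be seen. This background is set by the reporter probe sets, of which 2 were highest in 557. It was 2.41, 1.34 and 1.27 on the arrays of 557, against 0.43, 0.53 and 0.48 on those of 3806. The low share in 557 can therefore come from a raised background, and this was not told apart from dimmer probe sets. The linear scale with other pseudocounts was not run, since the values are logarithms.

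Leaving out each array in turn gave 888 to 1774 probe sets for LA1589, 529 to 825 by 2-fold and 3469 to 4176 among the landraces. Against the other 8 the ranges were 38 to 237 for 549, 1292 to 2404 for 557, 1441 to 2541 for 560, 19 to 115 for 571, 847 to 1723 for 572, 115 to 701 for 3806, 186 to 1068 for 3815, 56 to 574 for 3836 and 0 to 61 for 3842. At the preset correlation there were 10 list calls in single landraces with all arrays. With 1 array left out they ran from 5 without replicate 3 of 3836 to 18 without replicate 1 of 3815. There were 16 without replicate 3 of 571. The lowest probe set counts against the other 8 fell where an array of the landrace itself was absent, leaving it 2 arrays.

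Other settings moved counts by more than 1.5 times, and the cause was not tested. For LA1589, 1 mean per cultivar gave 111 probe sets (87 by 2-fold) and a random effect 228 (202). With the values as deposited 571 had 156. Median centring gave 6252 for the F test, 3858 for 557 and 2714 for 572. Array weights gave 771 for 549, 295 for 557, 694 for 571, 3255 for 3806, 1782 for 3815, 728 for 3836 and 1029 for 3842. The spike covariate gave 76 for 549, 286 for 557, 5 for 571, 339 for 572, 880 for 3806, 21 for 3836 and 1 for 3842. Without landrace 557 there were 589 for 3836 and 10 for 3842. With LA1589 in the comparison group 571 had 148. By fry 5 lists passed for LA1589, and 0 list calls in single landraces held with an estimated correlation.

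The replicates share only a number. For this check the mean of its cultivar was subtracted from each array, and the remainders were correlated between arrays of different cultivars. The median correlation was -0.006 over 135 pairs with the same number, against 0.004 for different numbers. By these remainders 7 of 30 arrays were closest to their own number. With the replicate number as a block, the counts were 1543 for LA1589, 636 by 2-fold, 3803 among the landraces, 125 for 549, 2263 for 557, 2239 for 560, 58 for 571, 1381 for 572, 517 for 3806, 793 for 3815, 305 for 3836 and 15 for 3842, and 0 lists passed for LA1589.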

Other observations

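The genes in this part were chosen after their values were seen, as the members of the ethylene and ripening list that passed in LA1589, and the check of them under other settings was made then too. In the signalling chain EIN2 was higher in LA1589 by 1.85 ± 0.32 (log2, SE, 3 against 27 arrays; limma adjusted p = 0.000227), and so were the transcription factor genes EIL1 (6.84 ± 0.27, SD, against 5.84; adjusted p = 0.000283), EIL4 (0.99 ± 0.24, 0.00518) and EIL3 (0.79 ± 0.18, 0.00396). CTR1, a negative regulator of the same chain, was higher too (1.13 ± 0.24, adjusted p = 0.00215), while EIL2 was lower (-1.04 ± 0.33, adjusted p = 0.032). Among MADS-box genes AG1 (1.68 ± 0.30, adjusted p = 0.000384), the ripening regulator RIN (0.71 ± 0.18, 0.00795; 8.24 ± 0.05 in LA1589 against 7.53) and LeSEP3 (0.60 ± 0.17, 0.0134) were higher, and TDR4 was lower (-0.90 ± 0.18, adjusted p = 0.000933).

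The 13 passing members of the list kept their direction with the values as deposited, with median centring and with each LA1589 array left out. As they were chosen for passing on these same arrays, this adds no independent support. The spike covariate was not part of this check. With 1 mean per cultivar 1 of the 13 passed, CTR1. With array weights 11 passed, all but ACO6 (adjusted p = 0.0939) and EIL2 (0.0572). EIL2 lost the threshold without replicate 1, 2 or 3 of LA1589 (adjusted p = 0.0826, 0.193 and 0.0599), LeSEP3 without replicate 2 (0.0957), and the ethylene synthesis gene ACO6 (1.53, adjusted p = 0.0116) without replicate 1 (0.187). ACS2 lost it without replicate 1 (adjusted p = 0.0730) or 3 (0.0573). The 2 other probe sets of ACO6 did not pass (-0.11 and 0.58). The list as a whole did not pass the camera test.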
